A study of Mus musculus with 12 samples.

How the data were processed

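RNA was sequenced from mouse spleen T cells after co-culture for 24 or 48 h with partner cells that the labels call Res. The partner cells carried either a control construct or a short hairpin RNA against Fabp7 (shFabp7), which gave 4 groups of 3 libraries, 12 in all. The cells had been kept in RPMI-1640 medium with serum and antibiotics, and total RNA had been isolated with a phenol-based reagent, per the labels' protocols.

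The deposited table holds raw read counts per gene symbol, whole numbers that were not normalized, for 53762 symbols in the 12 libraries, and no library was pooled. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.13 and HTSeq 0.6.1p1 were used with the mouse build GRCm39. The order and settings of these tools, the strand mode of counting and the annotation release were not given in the sources used here. Reads from a gene and an overlapping or antisense neighbour were therefore not separated here, and reads shared by near-identical paralogs or pseudogenes could have been split or dropped. The reference provided was of build GRCm38, so no coordinates were used. Of the symbols in the table, 92.9% were found in its list of gene names and 95.3% in that list or in the RefSeq names, and its transcripts were used only for GC content and length by symbol.

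Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 16945 genes, and libraries were scaled by TMM. The main test was edgeR 4.0.16 quasi-likelihood (robust dispersions, 1 coefficient per group, all 12 libraries in 1 fit) in R 4.3.3, with Benjamini-Hochberg adjustment over the 16945 genes and a threshold of 0.05. The 5 comparisons were the shFabp7 against the control partner at 24 h, the same at 48 h, the difference between these (an interaction contrast), and 48 h against 24 h with each partner. Log2 fold changes are given ± SE and levels as CPM (TMM-scaled) ± SD over the 3 libraries of a group, and adjusted p-values come from this test unless another is named.

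A set of 39 gene lists, covering T cell states, signalling and stress programmes, metabolism and the markers of other cell types, was tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. The lists held 714 symbols, of which 5 were renamed to the synonym the table uses and 1 was not found. Named genes were the Fabp family and Bmal1 (Arntl in the table), the 8 largest changes per direction for each partner effect, and the 6 largest per direction for the other comparisons. Up to 4 changed members of each list were named as well, or 2 where no member passed the threshold. Some of the genes that this rule selects are not reported here. Genes in the largest-change rule had a mean of at least 1 CPM in a compared group. Except for the interaction, the replicates of the compared groups also had to show no overlap in CPM. Predicted genes with Gm or Rik names, bare accessions, and immunoglobulin or T cell receptor segments were skipped. The largest changes named below are therefore the largest among the genes left by this rule. Lists, naming rule, tests and most alternatives were fixed before the data were examined.

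The alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter, a stricter filter (1 CPM in 3 samples and 100 counts in total), a fit on the compared groups alone, the replicate number as a block, a minimum fold of 1.2 (edgeR's glmTreat) and the omission of each library in turn. Scaling by library totals without TMM factors was added after the data had been seen. Other splits of the libraries were also tested, all 10 for a comparison of 3 with 3 and 100 drawn ones for the interaction.

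The procedure was tested on simulated data with 200 changed genes per comparison, as many up as down and all with a mean of at least 1 CPM. At a 2-fold change it recovered 96% of 50 such genes for the partner effect at 24 h, 100% at 48 h and 90% for the interaction. At a 1.25-fold change it recovered 52%, 60% and 22%. For time it recovered 60% at 1.25-fold with the control partner and 48% with the shFabp7 partner. Unchanged genes made up 13 of 177 calls at 24 h, 13 of 184 at 48 h and 9 of 154 for the interaction. For time they made up 11 of 181 and 5 of 168. These shares may not carry over to genes at lower levels or to data with more changed genes.

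Library totals were 32.0 to 40.6 M counts. A count of 0 was read as an upper limit of 3 counts, which covers counting error only. No cell sorting or purity measure of the T cells was given in the sources used here.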

Results

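Gene expression was measured by RNA sequencing in mouse spleen T cells that had been co-cultured with Res cells, and the stated question was which T cell genes differ when the partner cells carry shFabp7. There were 3 libraries for each of 4 groups, control partner at 24 h, shFabp7 partner at 24 h, control partner at 48 h and shFabp7 partner at 48 h. Total counts averaged 36.4 ± 2.32, 33.9 ± 1.97, 35.2 ± 1.13 and 36.8 ± 3.37 M (SD, n = 3), and 16945 genes were tested. Replicates differed beyond counting noise in every pair (chi-square per degree of freedom 4.34 to 14.2), so no library was counted as a duplicate. Nothing in the labels says that replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

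In the multidimensional scaling of the 12 libraries, time separated the samples along a dimension holding 70.0% of the variance and the partner along the next, with 4.73%.

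**Figure D1:**
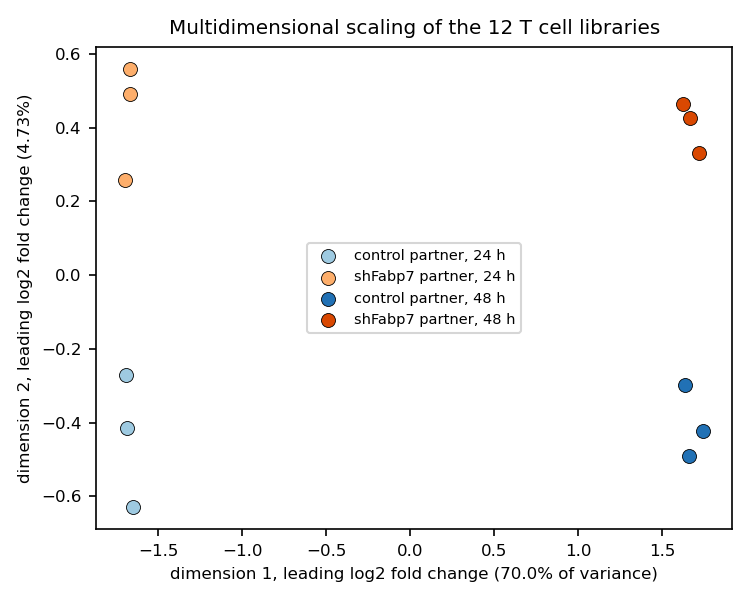
Multidimensional scaling of the 12 libraries on leading log2 fold changes, 1 point per library, coloured by group. Dimension 1 (70.0% of variance) parts 24 h from 48 h and dimension 2 (4.73%) parts the control from the shFabp7 partner at both times.

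Fabp7, the fatty acid binding protein gene targeted in the partner cells, was at or below the detection limit in every T cell library. It had 0 counts in all 6 libraries at 24 h and in the 3 libraries of the shFabp7 partner at 48 h, and 3, 1 and 1 counts in the 3 libraries of the control partner at 48 h. The limit of 3 counts lay between 0.0738 and 0.0939 CPM across these libraries, and Fabp7 was not tested. These counts do not check the knockdown in the partner cells. How the T cells were separated from the partner cells was not given in the sources used here, so transcripts carried over from partner cells, these Fabp7 counts included, were not excluded. Fabp5, which carries fatty acids in the cytosol of immune and epithelial cells, was the abundant member of the family. Its level was 43.3 ± 7.88 CPM with the control partner and 54.6 ± 4.64 CPM with the shFabp7 partner at 24 h (log2 fold change 0.33 ± 0.09, adjusted p = 0.0177). At 48 h it was 39.7 ± 0.521 against 57.1 ± 1.02 CPM (log2 0.52 ± 0.09, adjusted p = 7.2e-05). The 24 h call of Fabp5 was lost without control replicate 1 (adjusted p = 0.0708), without shFabp7 replicate 2 (adjusted p = 0.0572) and in a fit on the 24 h groups alone (adjusted p = 0.167). Over time Fabp5 did not pass the threshold with either partner (adjusted p = 0.222 and 0.522). It passed with the control partner without control replicate 3 at 24 h (adjusted p = 0.00921) and with the shFabp7 partner under library totals as scaling (adjusted p = 0.0328). Fabp3 had 0, 4, 27 and 34 counts over the 3 libraries of the groups in the order given above. It passed for time with each partner (adjusted p = 2.6e-04 and 0.00515) and for neither partner effect (adjusted p = 0.214 and 0.718). Fabp1, Fabp2 and Fabp4 had at most 5 counts in any group. Arntl, the core clock transcription factor also called Bmal1, was at 22.1 ± 0.931 against 21 ± 0.494 CPM at 24 h (log2 -0.08 ± 0.08, adjusted p = 0.589). At 48 h Arntl fell from 17.9 ± 0.78 to 14.9 ± 1.22 CPM (log2 -0.27 ± 0.08, adjusted p = 0.00808, or adjusted p = 0.0779 without shFabp7 replicate 3).

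At 24 h, some genes of T cell growth and activation were higher in T cells kept with the shFabp7 partner than in those kept with the control partner, and some interferon gamma response genes were lower. Il2, the T cell growth factor gene, rose from 36.8 ± 2.67 to 54.5 ± 6.44 CPM, and Ifng, the interferon gamma gene, from 124 ± 14.5 to 182 ± 19.3 CPM. Gbp4, an interferon-induced GTPase, fell from 848 ± 56.8 to 665 ± 41.4 CPM. In all, 1842 of 16945 genes changed, 1054 up and 788 down, and most changes were small, with a median absolute log2 fold change of 0.25. At least 2-fold changes were seen in 25 genes that rose and 59 that fell. Over all tested genes, the 3 libraries of a group all lay on 1 side of the other 3 in 27.5%, where chance gives 10%.

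The ribosome biogenesis and MYC target list, genes for making ribosomes under the growth regulator MYC, had 15 of 20 measured members up and none down, or 20 adjusted over the list alone (camera, adjusted p = 7.9e-20, or adjusted p = 0.123 with an estimated correlation). Rrp9, a ribosomal RNA processing factor, rose by log2 0.43 ± 0.06, adjusted p = 3.1e-05, Srm, spermidine synthase, by 0.44 ± 0.07, and Cad, an enzyme of pyrimidine synthesis, by 0.38 ± 0.07. Myc itself rose by 0.33 ± 0.06, adjusted p = 3.6e-04. In the T cell activation list 9 of 20 members rose and none fell (11 adjusted over the list alone, adjusted p = 0.123 with an estimated correlation). Il2 rose by log2 0.56 ± 0.08, adjusted p = 3.9e-05, Egr2, a transcription factor induced by the T cell receptor, by 0.37 ± 0.06, and Batf, which guides effector differentiation, by 0.30 ± 0.06. The cell cycle list had 13 of 32 members up and none down (21 adjusted over the list alone, adjusted p = 0.249 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at log2 0.49 ± 0.07, adjusted p = 3.1e-05 and the DNA replication regulator E2f1 at 0.39 ± 0.08. Among helper cytokines and regulators, 5 of 17 rose and none fell (8 up and 1 down adjusted over the list alone, adjusted p = 0.284 with an estimated correlation). The cytokine genes that rose included Il13 (0.34 ± 0.06, adjusted p = 6.6e-04), Il3 (0.58 ± 0.11) and Csf2 (0.35 ± 0.07). The helper cytokine list lost its camera call without control replicate 3 (adjusted p = 0.0609) and without shFabp7 replicate 2 (adjusted p = 0.0812).

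Of the sterol and fatty acid synthesis list 13 of 28 members rose at 24 h and none fell (17 adjusted over the list alone, adjusted p = 0.179 with an estimated correlation). Scd2, a fatty acid desaturase, rose by log2 0.31 ± 0.05, adjusted p = 3.9e-04, and the sterol gene Cyp51 by 0.27 ± 0.06. Of the apoptosis and p53 target list, 9 of 22 members rose and 2 fell (10 up and 3 down adjusted over the list alone, adjusted p = 0.179 with an estimated correlation). The p53 targets Phlda3 and Aen rose by 0.66 ± 0.09, adjusted p = 6.5e-05 and 0.34 ± 0.05, and Bax, which opens the outer mitochondrial membrane in apoptosis, by 0.32 ± 0.06. Oxidative phosphorylation had 7 of 28 members up and none down (15 adjusted over the list alone, adjusted p = 0.287 with an estimated correlation), for example the respiratory chain gene Uqcrc1 (0.25 ± 0.05, adjusted p = 0.00256). Heat shock chaperones had 7 of 14 up and none down (7 adjusted over the list alone, adjusted p = 0.123 with an estimated correlation), with Hspd1 at 0.23 ± 0.05, adjusted p = 0.00386. The immediate early and dissociation response list had 6 of 17 up and none down (7 adjusted over the list alone, adjusted p = 0.254 with an estimated correlation), with the stress factor Atf3 at 0.40 ± 0.06, adjusted p = 3.9e-05. The NF-kB list had 4 of 15 up and none down (7 up and 1 down adjusted over the list alone, adjusted p = 0.412 with an estimated correlation), with the activation marker Cd83 at 0.32 ± 0.06, adjusted p = 8.2e-04. Its camera call was also lost with library totals alone as scaling (adjusted p = 0.0506).

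The interferon gamma response and antigen presentation list fell at 24 h, with 13 of 24 members down and none up (14 adjusted over the list alone, adjusted p = 0.254 with an estimated correlation). On the log2 scale Gbp4 fell by 0.35 ± 0.06, adjusted p = 1.4e-04. The related GTPase genes Gbp7 and Iigp1 were at -0.32 ± 0.06 and -0.28 ± 0.06, and near-identical copies in this family make single members uncertain. Of the naive and memory T cell list, 3 of 16 fell and 1 rose (5 down and 1 up adjusted over the list alone, adjusted p = 0.399 with an estimated correlation). Among the genes that fell were the interleukin 7 receptor gene Il7r (-0.37 ± 0.07, adjusted p = 6.8e-04) and the lymphocyte egress receptor gene S1pr1 (-0.32 ± 0.06). This list lost its camera call without control replicate 3 (adjusted p = 0.0939) or shFabp7 replicate 2 (adjusted p = 0.092). Nt5e, the adenosine-generating enzyme CD73, fell by 0.66 ± 0.07, adjusted p = 5.5e-07 on the log2 scale, and the chemokine gene Ccl17 by 0.98 ± 0.11, adjusted p = 2.1e-06.

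Some markers of other cell types changed with the partner at 24 h. The neutrophil list had a median log2 fold change of -0.70 with 1 of 8 measured members down, and the monocyte and macrophage list -0.34 with none of 14 past the threshold. The B cell list had a median of -0.22 with 2 of 20 down, and the dendritic cell list -0.22 with 3 of 9 down and 1 up. Adjusted over the list alone, the numbers down were 1, 0, 4 and 3. With an estimated correlation these lists had adjusted p = 0.338, 0.232, 0.416 and 0.284. Library totals alone as scaling ended the camera calls of the neutrophil, monocyte and B cell lists (adjusted p = 0.0652, 0.0854 and 0.0535). Leaving out a library ended the neutrophil call (control replicate 2, adjusted p = 0.0806) and the dendritic cell call (shFabp7 replicate 2, adjusted p = 0.0565). It ended the monocyte call without control replicate 1 or 2 or shFabp7 replicate 2 (adjusted p up to 0.0963) and the B cell call without replicate 2 or 3 of either group (adjusted p up to 0.136). H2-DMb2, a class II peptide loading gene, fell by 0.57 ± 0.09, adjusted p = 2.6e-04 on the log2 scale and the class II gene H2-Aa by 0.39 ± 0.07, adjusted p = 5.4e-04.

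The largest increases at 24 h that held whichever library was left out were in Edn1, the endothelin-1 gene (0.445 ± 0.154 to 1.42 ± 0.317 CPM, log2 1.67 ± 0.37, adjusted p = 0.0033) and in Lipg, endothelial lipase (1.32 ± 0.20, adjusted p = 7.3e-05). They were followed by the homeobox gene Nkx1-1 (1.10 ± 0.25) and the myosin heavy chain gene Myh7 (0.90 ± 0.17). The largest such decreases were in Arg1, arginase 1 (1.5 ± 0.151 to 0.607 ± 0.148 CPM, log2 -1.30 ± 0.30, adjusted p = 0.0051), and in the neuropeptide gene Qrfp (-1.05 ± 0.26). Next came the zinc finger gene Zfp488 (-1.01 ± 0.23) and the pseudogene Xlr4e-ps (-1.0 ± 0.24), whose reads may be shared with related genes. The calls of Adm (0.94 ± 0.23) and Slc13a3 (0.90 ± 0.22) were lost without shFabp7 replicate 2 (adjusted p = 0.0501 and 0.0744). Pvrig (-1.05 ± 0.28) lost its call without control replicate 3 or shFabp7 replicate 2, and the histone gene H4c9 (0.90 ± 0.26) without either of these or control replicate 1. Ppfibp2 (-1.0 ± 0.31) lost its call without any of these 3 or shFabp7 replicate 3, Cpne8 (-1.05 ± 0.33) without any library but control replicate 2, and S100a9 (-1.20 ± 0.38), a neutrophil calcium-binding protein gene, without any library but shFabp7 replicate 3. In these 5 genes the adjusted p reached 0.0780, 0.114, 0.157, 0.205 and 0.163.

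The share of increases at 24 h depended on the scaling. Of the changed genes 57.2% rose with TMM, against 1581 up and 619 down with RLE scaling (71.9%), 1852 and 681 with DESeq2 (73.1%), 753 and 1035 with upper-quartile scaling (42.1%) and 604 and 1214 with library totals alone (33.2%). Without the filter on low counts 1534 rose and 680 fell (69.3%), and without 1 library 64.2 to 69.3% rose. The count fell to 949 without control replicate 1 and to 1045 without shFabp7 replicate 1, and 14 genes passed when the fold had to exceed 1.2.

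At 48 h the partner effect covered more genes, and transcripts of ribosome biogenesis, MYC targets and protein folding factors were higher with the shFabp7 partner. Srm, spermidine synthase, rose from 66.3 ± 9.02 to 133 ± 2.46 CPM and Calr, the endoplasmic reticulum chaperone calreticulin, from 519 ± 36.3 to 805 ± 21 CPM. Ifng rose from 276 ± 14.6 to 473 ± 10.0 CPM and Gzmb, the killer cell protease granzyme B, from 1401 ± 29.4 to 1901 ± 46.3 CPM. Of 16945 genes 5352 changed, 3380 up and 1972 down, with a median absolute log2 fold change of 0.32, and 75 rose and 160 fell by at least 2-fold. Over all tested genes, the groups did not overlap in 44.0%, where chance gives 10%.

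**Figure D2:**
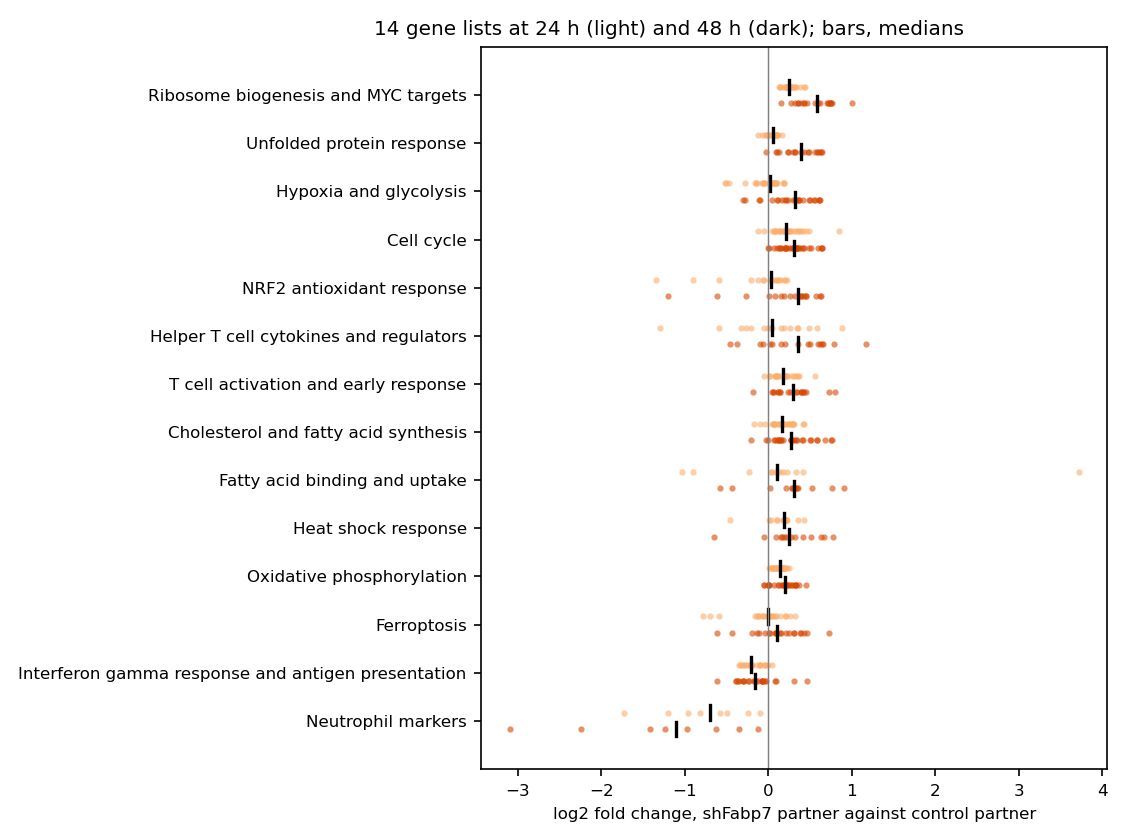
Log2 fold changes, shFabp7 against control partner, of the measured members of 14 gene lists at 24 h (light points) and 48 h (dark points), with a bar at each median. The ribosome biogenesis median was 0.25 at 24 h and 0.58 at 48 h, that of the unfolded protein response 0.06 and 0.39, and that of the interferon gamma response -0.21 and -0.16, each with the same sign under TMM, RLE, upper-quartile and total-count scaling (the point far to the right is Fabp3, with 0 against 4 counts at 24 h).

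Ribosome biogenesis and MYC target genes rose in 19 of 20 members and fell in none (20 adjusted over the list alone), and the list held with an estimated correlation (adjusted p = 0.0295 with an estimated correlation). The transcripts of ribosomal proteins themselves, looked at after this result, made up 7.65 ± 0.453% of counts with the control and 6.48 ± 0.0861% with the shFabp7 partner at 48 h, and 7.53 ± 0.518% and 7.81 ± 0.335% at 24 h (SD, n = 3). Srm rose by log2 1.0 ± 0.07, adjusted p = 9.8e-11, and Nolc1, Rrp12 and Bop1, which act in the nucleolus in ribosome assembly, by 0.74 ± 0.06, 0.73 ± 0.06 and 0.70 ± 0.06. The unfolded protein response list had 16 of 19 members up and none down (16 adjusted over the list alone) and also held (adjusted p = 0.00983 with an estimated correlation). Among its endoplasmic reticulum folding factors, Calr rose by 0.63 ± 0.05, adjusted p = 1.4e-10, Sdf2l1 by 0.64 ± 0.06, Hyou1 by 0.62 ± 0.06 and Manf by 0.60 ± 0.05. These were the only list calls for either partner effect that held with an estimated correlation, out of 16 at 24 h and 15 at 48 h. Heat shock chaperones rose in 10 of 14 members and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.0794 with an estimated correlation), led by Hsph1 (0.77 ± 0.05, adjusted p = 4.7e-12) and Hspd1 (0.66 ± 0.05).

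At 48 h hypoxia and glycolysis genes were up in 18 of 25 and down in none (19 up and 1 down adjusted over the list alone, adjusted p = 0.0985 with an estimated correlation). Those that rose included the glycolytic enzyme genes Pgam1 (0.62 ± 0.06, adjusted p = 4.0e-10), Hk2 (0.61 ± 0.06) and Pfkl (0.56 ± 0.06) and the oxygen sensor gene Egln3 (0.60 ± 0.06). Sterol and fatty acid synthesis genes were up in 18 of 28 and down in 1 (19 and 1 adjusted over the list alone, adjusted p = 0.215 with an estimated correlation). Examples are Idi1 (0.58 ± 0.06, adjusted p = 2.6e-08) and Acly (0.50 ± 0.05). Fatty acid binding and uptake genes were up in 8 of 13 and down in 1 (the same numbers adjusted over the list alone, adjusted p = 0.24 with an estimated correlation). The acyl-CoA synthetase gene Acsl5 rose by 0.36 ± 0.05, adjusted p = 8.4e-07, and the fatty acid transporter gene Slc27a1 fell by 0.57 ± 0.09 on the log2 scale. NRF2 antioxidant genes were up in 10 of 18 and down in 1 (11 and 2 adjusted over the list alone, adjusted p = 0.268 with an estimated correlation). Increases were seen in the pentose phosphate enzyme genes Pgd (0.62 ± 0.06, adjusted p = 5.3e-10), G6pdx (0.45 ± 0.05) and Tkt (0.45 ± 0.05) and the thioredoxin reductase gene Txnrd1 (0.57 ± 0.06). Oxidative phosphorylation genes were up in 18 of 28 and down in none (21 adjusted over the list alone, adjusted p = 0.365 with an estimated correlation), such as Uqcrc1 (0.46 ± 0.05, adjusted p = 4.0e-08). Of the ferroptosis list, 8 of 23 rose and 1 fell (the same numbers adjusted over the list alone, adjusted p = 0.264 with an estimated correlation). The members that rose included Tfrc, the iron import receptor (0.73 ± 0.07, adjusted p = 7.7e-09) and Ftl1, an iron storage protein (0.31 ± 0.05). They also included Dhodh, a mitochondrial pyrimidine synthesis enzyme that limits lipid peroxidation (0.47 ± 0.07), and Trp53 (0.40 ± 0.06), so that genes known to favour and to oppose ferroptosis moved the same way. The ferroptosis call, adjusted p = 0.0352 by camera, was lost without control replicate 1 (adjusted p = 0.0509) and with library totals alone as scaling (adjusted p = 0.051).

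The cell cycle list at 48 h had 25 of 32 members up and none down (27 adjusted over the list alone, adjusted p = 0.215 with an estimated correlation). Its members included the replication genes Rrm2 (0.60 ± 0.05, adjusted p = 5.3e-10) and Mcm4 (0.49 ± 0.05) and the mitosis genes Plk1 (0.63 ± 0.06) and Cdc20 (0.65 ± 0.07). T cell activation genes were up in 13 of 20 and down in 1 (15 and 1 adjusted over the list alone, adjusted p = 0.153 with an estimated correlation). Il2 was at 0.80 ± 0.09, adjusted p = 8.2e-08 and the interleukin 2 receptor gene Il2ra at 0.46 ± 0.06. Helper cytokine genes were up in 8 of 17 and down in 1 (the same numbers adjusted over the list alone, adjusted p = 0.24 with an estimated correlation), with Il3 (1.17 ± 0.11, adjusted p = 1.3e-09), Il13 (0.79 ± 0.06) and Csf2 (0.65 ± 0.06). Immediate early and dissociation response genes were up in 10 of 17 and down in 1 (the same numbers adjusted over the list alone, adjusted p = 0.328 with an estimated correlation), with Atf3 at 0.58 ± 0.06, adjusted p = 1.5e-09. The cytotoxic effector list did not pass as a list (camera, adjusted p = 0.0535), and 7 of its 20 members rose and 2 fell (8 and 2 adjusted over the list alone). Ifng rose by 0.78 ± 0.07, adjusted p = 1.5e-08, the perforin gene Prf1 by 0.57 ± 0.06, Gzmb by 0.44 ± 0.05 and the granzyme inhibitor gene Serpinb9 by 0.49 ± 0.05.

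**Figure D3:**
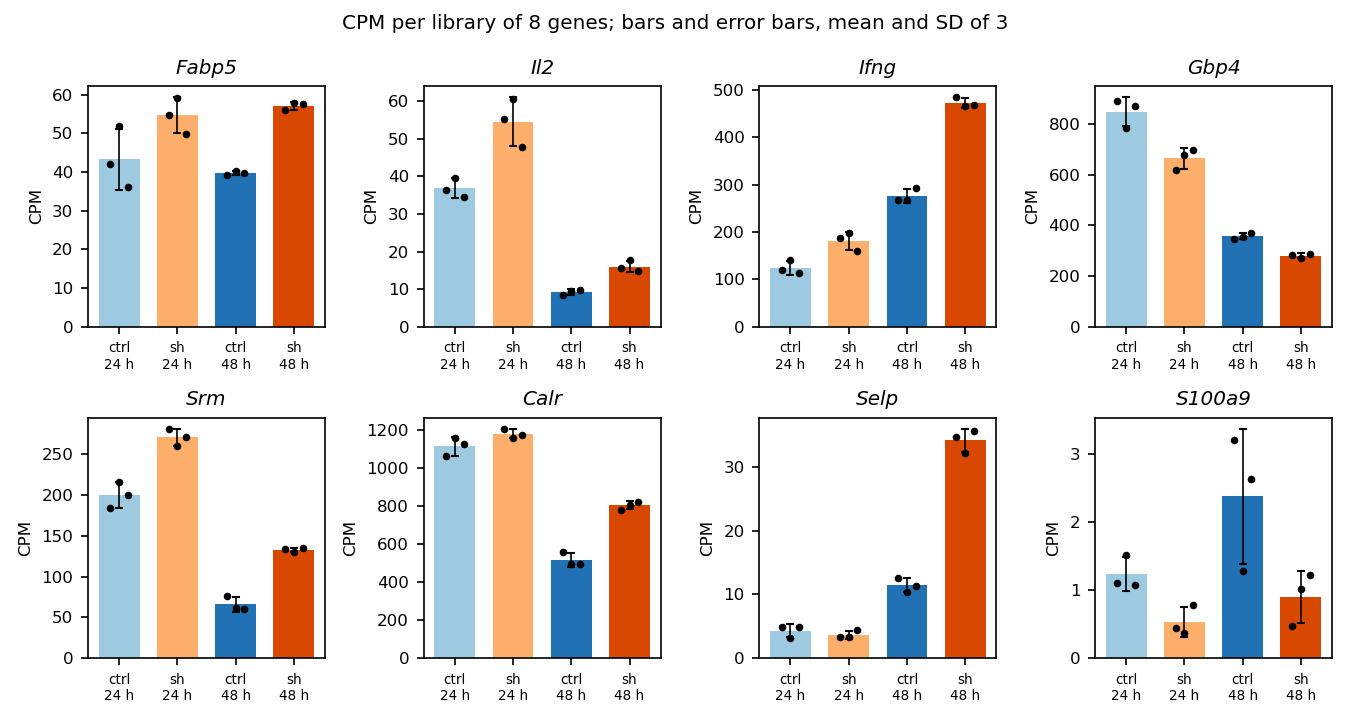
CPM of 8 genes in each of the 12 libraries (points), with the group mean (bar) and SD (error bar, n = 3). Ifng rose with the shFabp7 partner at both times while Gbp4 fell, and Selp stood at 34.1 ± 1.78 CPM with the shFabp7 partner at 48 h against 11.5 ± 1.09 CPM with the control partner.

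The interferon gamma response and antigen presentation list fell at 48 h, with 12 of 24 members down and 1 up (14 and 1 adjusted over the list alone, adjusted p = 0.378 with an estimated correlation). Nlrc5, the transactivator of class I antigen presentation genes, fell by 0.39 ± 0.05, adjusted p = 1.2e-06 on the log2 scale, Irf1 by 0.31 ± 0.06 and Gbp4 by 0.35 ± 0.06. Neutrophil markers had a median of -1.11, with 4 of 8 measured members down and none up (the same numbers adjusted over the list alone, adjusted p = 0.253 with an estimated correlation). These were S100a8 (-2.24 ± 0.40, adjusted p = 3.9e-05), S100a9 (-1.41 ± 0.32), Lcn2 (-0.98 ± 0.24) and Ngp (-3.10 ± 0.95), whose call was lost without control replicate 2 (adjusted p = 0.0576) or shFabp7 replicate 1 (adjusted p = 0.0705). Their levels were low, S100a9 at 2.38 ± 0.991 against 0.904 ± 0.385 CPM and Ngp at 0.402 ± 0.232 against 0.0453 ± 0.0186 CPM, so the size of the Ngp change rests on few counts. The monocyte and macrophage list (median -0.19, 3 of 14 down) and the B cell list (median 0.01, mean -0.10, 2 of 20 down) did not pass at 48 h (camera, adjusted p = 0.113 and 0.175), and H2-DMb2 fell by 0.96 ± 0.08, adjusted p = 7.7e-10 on the log2 scale. At 48 h Nt5e fell by 1.04 ± 0.07, adjusted p = 4.7e-12 on the log2 scale.

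The largest single increases at 48 h were in Ehd2, a membrane-shaping ATPase of caveolae (2.61 ± 0.334 to 8.41 ± 0.52 CPM, log2 1.68 ± 0.18, adjusted p = 8.0e-09), and the potassium channel gene Kcnk10 (1.65 ± 0.40). Large increases were also seen in Selp, the adhesion molecule P-selectin (11.5 ± 1.09 to 34.1 ± 1.78 CPM, log2 1.57 ± 0.10, adjusted p = 5.4e-12), and the activin subunit gene Inhba (1.41 ± 0.14). The peptide hormone genes Npw (1.38 ± 0.20) and Adm (1.38 ± 0.17) and the tumour necrosis factor receptor family gene Tnfrsf19 (1.37 ± 0.33) rose as well. The phosphodiesterase gene Pde1a (1.52 ± 0.41) lost its call without shFabp7 replicate 3 (adjusted p = 0.0596). The largest decreases besides the neutrophil genes that held whichever library was left out were in Ccr9, a gut homing chemokine receptor (32.7 ± 2.38 to 10.9 ± 0.367 CPM, log2 -1.59 ± 0.09, adjusted p = 6.7e-14), Ypel1 (-1.56 ± 0.30) and Cspg5, a chondroitin sulfate proteoglycan (-1.38 ± 0.28). The macrophage chitinase-like gene Chil3 (-2.05 ± 0.66) lost its call without replicate 1 of either group, control replicate 3 or shFabp7 replicate 2 (adjusted p up to 0.109). Tppp (-1.56 ± 0.49) lost it without control replicate 3 or shFabp7 replicate 3 (adjusted p up to 0.0927), and Cfap46 (-1.40 ± 0.42) without shFabp7 replicate 3 (adjusted p = 0.0893).

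At 48 h 63.2% of the changed genes rose with TMM scaling, against 2125 up and 3195 down with upper-quartile scaling (39.9%) and 2157 up and 3168 down with library totals alone (40.5%). When the fold had to exceed 1.2, 1005 genes passed.

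The partner effects at the 2 times overlapped. Of the genes that rose, 873 did so at both times, against 210.2 for independent lists, and of those that fell 456, against 91.7. Another 17 genes changed in opposite directions, and 92.9% of the genes changed at 24 h had the same sign at 48 h. Across all tested genes the log2 fold changes had a Pearson correlation of 0.248 and a Spearman correlation of 0.418. These correlations are across genes, which are not independent replicates. Among genes with at least 1 CPM in 3 samples they were 0.455 and 0.545.

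**Figure D4:**
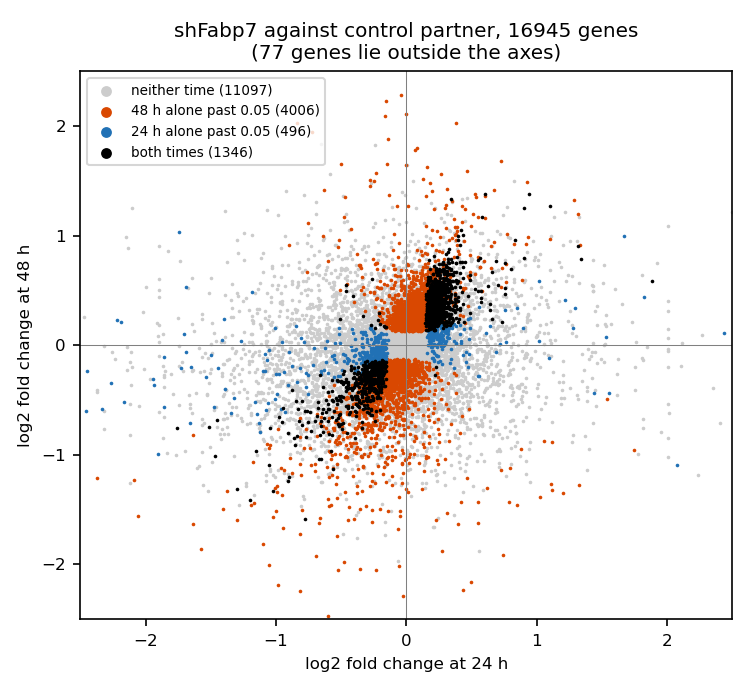
Log2 fold change with the shFabp7 against the control partner at 24 h (horizontal) and 48 h (vertical), 1 point per gene, coloured by the times at which the gene passed the threshold. Of 16945 genes 1346 passed at both times, 4006 at 48 h alone and 496 at 24 h alone, and 77 genes lie outside the axes.

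The partner effect differed between 48 h and 24 h for genes of protein folding and glycolysis, and was higher at 48 h. The interaction test asked this directly and found 949 genes, 750 with a higher and 199 with a lower partner effect at 48 h, a split that did not hold when a 24 h library was left out (50.5 to 60.1% higher, against 79.0%). The unfolded protein response list had 12 of 19 members higher and none lower (16 adjusted over the list alone), with a median difference of 0.34 on the log2 scale, and hypoxia and glycolysis 17 of 25 higher and none lower (18 adjusted over the list alone), with a median of 0.32. Both held with an estimated correlation (adjusted p = 0.00363 and 0.0378 with an estimated correlation). Over time the unfolded protein response list fell with either partner, but less with shFabp7 (medians -0.42 with the control and -0.18 with the shFabp7 partner). The hypoxia and glycolysis list rose with either, and more with shFabp7 (0.34 and 0.55).

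The difference was 0.55 ± 0.08, adjusted p = 4.8e-05 for Calr, 0.51 ± 0.07, adjusted p = 4.8e-05 for Manf, 0.53 ± 0.08 for Sdf2l1 and 0.51 ± 0.08 for Hyou1. For Slc16a3, a lactate exporter gene that fell at 24 h (-0.46 ± 0.09, adjusted p = 0.00104), it was 1.02 ± 0.11, adjusted p = 2.3e-06. The Slc16a3 level at 48 h was 86.1 ± 10.7 CPM with the control and 126 ± 5.55 CPM with the shFabp7 partner. Eno1, Pfkl and Egln3 differed by 0.45 ± 0.07, 0.49 ± 0.08 and 0.53 ± 0.08. Ribosome biogenesis had 12 of 20 members higher (15 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation). Srm differed by 0.56 ± 0.10, adjusted p = 8.8e-04 and Nolc1 by 0.46 ± 0.08. NRF2 antioxidant genes were higher in 6 of 18 (7 adjusted over the list alone, adjusted p = 0.406 with an estimated correlation). Among them were Pgd (0.47 ± 0.08, adjusted p = 5.4e-04) and Txnrd1 (0.46 ± 0.08). The apoptosis and p53 target list had 4 of 22 members lower and none higher (5 lower and 1 higher adjusted over the list alone, adjusted p = 0.482 with an estimated correlation). Among these were Bbc3, a p53-induced activator of apoptosis (-0.61 ± 0.11, adjusted p = 0.00167), Sesn1 (-0.37 ± 0.08) and Bcl2l11 (-0.35 ± 0.08), and by fry the list did not pass (adjusted p = 0.269). The heat shock list had 2 of 14 members higher and 1 lower (5 and 1 adjusted over the list alone) and the ferroptosis list 3 of 23 higher (6 adjusted over the list alone), with adjusted p = 0.42 with an estimated correlation for each. Hsph1 differed by 0.60 ± 0.08, adjusted p = 1.7e-05 and Tfrc by 0.51 ± 0.10, adjusted p = 0.00215. The heat shock call ended without control replicate 2 at 24 h, any shFabp7 replicate at 24 h or shFabp7 replicate 1 at 48 h (adjusted p up to 0.252). The ferroptosis call ended without replicate 2 or 3 of either group at 24 h, control replicate 1 or shFabp7 replicate 3 at 48 h (adjusted p up to 0.138). Both ended with library totals alone as scaling (adjusted p = 0.0518 for each), and the heat shock call without the filter (adjusted p = 0.0724).

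Among single genes, Selp (1.8 ± 0.18, adjusted p = 4.7e-07) and Inhba (1.21 ± 0.21, adjusted p = 5.7e-04) were, among the 6 largest differences in that direction, those that held whichever library was left out. Slc16a3 and Egln3 held as well. Of the 83 named calls for the difference, list members included, 33 held in every such fit and 50 were lost in at least 1. The count of 949 moved by over 1.5 times in most fits without a library. At 24 h it was 513 and 589 without control replicates 2 and 3, and 628, 319 and 342 without shFabp7 replicates 1, 2 and 3. At 48 h it was 1680, 588 and 564 without control replicates 1, 2 and 3, and 589, 569 and 569 without shFabp7 replicates 1, 2 and 3. The split was 390 higher and 259 lower, 259 and 254, and 349 and 240 without control replicates 1, 2 and 3 at 24 h. It was 336 and 292, 183 and 136, and 198 and 144 without shFabp7 replicates 1, 2 and 3 at 24 h, and 79.3 to 83.5% were higher without a 48 h library. With upper-quartile scaling the split was 341 higher and 356 lower, with library totals alone 446 and 275 and without the filter 483 and 341, against 750 and 199 in the main test. In all, 13 genes passed when the difference had to exceed 1.2-fold.

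Between 24 and 48 h cell cycle transcripts rose with either partner. Mki67, a marker of dividing cells, rose from 39.2 ± 1.22 to 763 ± 60.6 CPM with the control partner and from 41.5 ± 4.47 to 803 ± 42.7 CPM with the shFabp7 partner. Gzmb rose from 177 ± 14.3 to 1401 ± 29.4 CPM and from 211 ± 3.16 to 1901 ± 46.3 CPM. Gbp2, an interferon-induced GTPase, fell from 962 ± 50.9 to 301 ± 17.8 CPM and from 819.5 ± 44.1 to 257 ± 19.9 CPM. With the control partner 11478 genes changed, 6063 up and 5415 down, and 3070 rose and 877 fell by at least 2-fold. With the shFabp7 partner 11207 changed, 6085 up and 5122 down, and 3067 rose and 735 fell by at least 2-fold. The groups did not overlap in 68.6% and 71.4% of all tested genes, where chance gives 10%. Both sets shared 5229 genes that rose and 4517 that fell, against 2177 and 1637 for independent lists, and 35 genes changed in opposite directions.

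The cell cycle list had 30 of 32 members up and 1 down with either partner (medians 2.83 and 2.84 on the log2 scale), and held for both (adjusted p = 0.0203 and 0.0121 with an estimated correlation), the only list call over time that did. Adjusted over the list alone, 30 rose with either partner, and 2 and 1 fell. Mki67 rose by 4.28 ± 0.07, adjusted p = 4.4e-29 with the control partner, and the mitosis genes Tpx2 and Ccnb1 by 3.95 ± 0.07 and 3.94 ± 0.08. All 20 ribosome biogenesis members fell with each partner, also adjusted over the list alone (adjusted p = 0.0812 and 0.119 with an estimated correlation), for example Rrp12 (-1.63 ± 0.06, adjusted p = 6.9e-22 with the control partner). The interferon gamma response list had 22 of 24 members down with either partner, and 1 and 2 up, the same numbers adjusted over the list alone (adjusted p = 0.176 and 0.155 with an estimated correlation). The type I interferon list had 20 and 19 of 25 down and 0 and 1 up, the same numbers adjusted over the list alone (adjusted p = 0.512 and 0.568 with an estimated correlation). Gbp2 fell by 1.67 ± 0.06, adjusted p = 2.5e-22 on the log2 scale with the control partner and the interferon-induced gene Rtp4 by 2.12 ± 0.09, adjusted p = 8.8e-21. Of the heat shock list 11 and 10 of 14 fell and 2 rose (adjusted p = 0.0812 and 0.119 with an estimated correlation), the same numbers adjusted over the list alone. T cell identity genes fell in 15 of 22 members with either partner and rose in 3 and 4, the same numbers adjusted over the list alone (adjusted p = 0.186 and 0.179 with an estimated correlation). Those that fell included the co-stimulatory receptor gene Cd27 (-1.45 ± 0.05, adjusted p = 7.1e-22 with the control partner) and Cd8a (-1.13 ± 0.05).

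Over time the cytotoxic effector list had 11 of 20 members up with either partner and 6 and 8 down, the same numbers adjusted over the list alone (adjusted p = 0.186 and 0.155 with an estimated correlation). Gzmb rose by 2.98 ± 0.06, adjusted p = 1.9e-29 and 3.17 ± 0.06, adjusted p = 2.6e-30 with the control and the shFabp7 partner, Gzmc by 3.18 ± 0.14 and 3.31 ± 0.14, and Tnf fell by 1.34 ± 0.06 and 1.34 ± 0.06 on the log2 scale. Hypoxia and glycolysis genes were up in 17 and 22 of 25 and down in 3 and 2, the same numbers adjusted over the list alone (adjusted p = 0.298 and 0.119 with an estimated correlation). The glucose transporter gene Slc2a3 was at 2.03 ± 0.05, adjusted p = 3.5e-26 and 2.39 ± 0.05, adjusted p = 6.0e-28. Fatty acid oxidation genes rose in 14 of 20 members and fell in 2 with either partner, also adjusted over the list alone (adjusted p = 0.186 and 0.156 with an estimated correlation). Cpt1a, which brings fatty acids into mitochondria, rose by 1.36 ± 0.06, adjusted p = 5.2e-20 with the control partner. Lipid droplet genes rose in 8 of 12 with either partner and fell in 3 and 2, with 8 up and 3 down for each adjusted over the list alone (adjusted p = 0.176 and 0.155 with an estimated correlation). Among them was the droplet coat gene Plin2 (1.56 ± 0.08, adjusted p = 2.2e-18 with the control partner). Apoptosis and p53 targets rose in 16 and 14 of 22 and fell in 4 and 5, with 16 up for each adjusted over the list alone (adjusted p = 0.209 and 0.355 with an estimated correlation). Without the filter on low counts the cytotoxic and the lipid droplet lists did not pass with the shFabp7 partner (adjusted p = 0.0789 and 0.0711).

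T cell activation genes were down in 13 and 12 of 20 members and up in 6 and 8, the same numbers adjusted over the list alone (adjusted p = 0.395 and 0.504 with an estimated correlation). Il2 fell by 2.00 ± 0.09, adjusted p = 7.1e-19 and 1.77 ± 0.08, adjusted p = 3.4e-18 on the log2 scale, and the early activation marker Cd69 by 1.32 ± 0.06 and 1.62 ± 0.06. With the shFabp7 partner the activation list did not pass with library totals alone as scaling (adjusted p = 0.0809). With the control partner 5 further lists passed, each lower at 48 h as a list. These were the unfolded protein response (15 of 19 down, 1 up), NRF2 antioxidant genes (13 of 18 down, 2 up), chemokines and their receptors (11 of 20 down, 4 up), oxidative phosphorylation (21 of 28 down, none up) and regulatory T cell genes (6 of 12 down, 3 up). Adjusted over the list alone, 15, 13, 12, 21 and 6 were down and 1, 2, 4, 0 and 3 up, and the lists had adjusted p = 0.0812, 0.512, 0.319, 0.765 and 0.262 with an estimated correlation. With the shFabp7 partner these lists had camera adjusted p = 0.0735, 0.345, 0.063, 0.0735 and 0.0574. The oxidative phosphorylation call ended without control replicate 2 at 24 h (adjusted p = 0.101) and with library totals alone as scaling (adjusted p = 0.195). The regulatory T cell call ended without control replicate 3 at 24 h (adjusted p = 0.0587) or at 48 h (adjusted p = 0.0621), with library totals alone (adjusted p = 0.0861) and without the filter (adjusted p = 0.0641).

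Several of the largest changes over time were in genes nearly absent at 24 h, which are given as levels. Il24, a cytokine of the interleukin 10 family, rose from 0.514 ± 0.272 to 66.7 ± 4.90 CPM with the control and from 0.761 ± 0.246 to 109.6 ± 3.47 CPM with the shFabp7 partner. Dnm1, a dynamin of endocytosis, rose from 0.0663 ± 0.0428 to 13.8 ± 1.06 CPM with the control partner, and Dthd1 from 0.0288 ± 0.00178 to 7.22 ± 1.41 CPM. Prph, an intermediate filament gene, had 0 counts at 24 h and 1.22 ± 0.147 and 1.05 ± 0.287 CPM at 48 h with the control and the shFabp7 partner. With the shFabp7 partner the insulin-regulated glucose transporter gene Slc2a4 and the glutamine transporter gene Slc38a3 had 0 counts at 24 h and 1.97 ± 0.273 and 1.6 ± 0.214 CPM at 48 h. With the control partner both rose likewise, from 3 and 1 counts at 24 h to 1.63 and 1.18 CPM at 48 h. The largest declines included the chemokine gene Ccl1 (-2.68 ± 0.16, adjusted p = 4.0e-08 with the control and -3.27 ± 0.17, adjusted p = 9.7e-09 with the shFabp7 partner), and the vascular growth factor receptor gene Kdr (-2.94 ± 0.27 and -2.64 ± 0.27). Others were Apol7c (-3.28 ± 0.10 with the control partner) and Grwd1, a ribosome assembly factor (-2.60 ± 0.07 with the control partner). Rprl3 (-3.17 ± 0.38 with the control and -3.18 ± 0.35 with the shFabp7 partner) and Nkx1-1 (-2.79 ± 0.34 and -2.62 ± 0.28) fell with either partner, and Ifit3 was at -2.47 ± 0.16 with the shFabp7 partner.

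Scaling moved the split of the time effects. The median of all tested genes was 0.04 with the control and 0.06 with the shFabp7 partner by TMM, 0.14 and 0.10 by upper-quartile scaling and 0.23 and 0.21 by library totals alone. With library totals 7746 genes rose and 3781 fell with the control partner (67.2% up, against 52.8% with TMM), and 7483 rose and 3789 fell with the shFabp7 partner (66.4% against 54.3%).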

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

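The setting of library totals was chosen after the main result but before its own values, and the tests of the position on the time course, of the scaling behind the lower interferon gamma response, of the shares of their level that lists lost, and both tests of the neutrophil markers were chosen only after the result was seen.

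The partner effect differed between 48 h and 24 h, by the interaction test itself, for 949 genes and 7 gene lists. The median difference on the log2 scale was 0.34 for the unfolded protein response, 0.32 for hypoxia and glycolysis, 0.30 for ribosome biogenesis and MYC targets, 0.23 for NRF2 antioxidant genes, 0.13 for ferroptosis, 0.12 for heat shock and -0.0370 for apoptosis and p53 targets. The median of the last list was near 0 and below the 0.0397 of all tested genes. Its members past the threshold were all lower, but most members did not pass, so the list as a whole shifted little. With an estimated correlation the first 2 lists passed and the other 5 did not.

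Among the genes with the largest differences, Selp (1.8), Inhba (1.21) and Ccr9 (-0.81) passed whichever library was left out. Gspt2 (1.48) and H2bc4 (-1.87) lost their calls without shFabp7 replicate 3 at 24 h (adjusted p = 0.0551 and 0.0554) and Tmprss4 (-2.01) without shFabp7 replicate 2 at 24 h (adjusted p = 0.0512). Pdgfa (1.37) lost its call without control replicate 1 or shFabp7 replicate 2 or 3 at 24 h (adjusted p up to 0.0728), and Dbn1 (2.46) without any library at 24 h but control replicate 3 (adjusted p up to 0.120). Cspg5 (-1.33) kept its call only without control replicate 2 or shFabp7 replicate 3 at 24 h, control replicate 1 or 2 or shFabp7 replicate 3 at 48 h (adjusted p otherwise up to 0.118). Tgfb3 (1.75) kept its call only without shFabp7 replicate 1 at 24 h, control replicate 1 or 2 or shFabp7 replicate 1 at 48 h (otherwise up to 0.201). Dnm1 (-2.03) kept it only without control replicate 3 at 24 h, control replicate 1 or 3 or shFabp7 replicate 1 at 48 h (otherwise up to 0.134). Rmrp (-1.84) kept it only without control replicate 2 or shFabp7 replicate 2 at 24 h or control replicate 1 or 2 at 48 h (otherwise up to 0.180). Rpl31-ps15 (-1.91) kept it only without control replicate 2 or shFabp7 replicate 1 at 24 h or control replicate 1 at 48 h (otherwise up to 0.176). Dbn1 (0.0419 CPM with the shFabp7 partner), Dnm1 (0.0663 with the control partner), Tmprss4 (0.105 with the control partner) and Tgfb3 (0.146 with the shFabp7 partner) were near absent at 24 h, so their differences rest on few counts and have no exact size. Rpl31-ps15 is a pseudogene and H2bc4 a histone gene with near-identical copies, so shared reads stay open for both.

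Of 100 splits of the libraries, the real one included, 11 gave as many interaction genes as the real 949 (highest other 5595) and 76 gave as many lists as the real 7 (highest other 21), so chance was not excluded for either number by this count. The splits differed in kind. The 75 that mixed the groups at both times gave at most 1 gene, and the 10 that mixed them at 48 h alone gave 0. In these splits the real differences entered the spread within the mixed groups. That lowers the number of genes called, so the low numbers are given no weight. The 13 that mixed the groups at 24 h and left those at 48 h whole gave 684 to 3961, and the split that exchanged the whole groups at 1 time gave 5595. The large numbers therefore point to a structure of the samples, the partner effect at 48 h, which these splits carry into the contrast.

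For the other comparisons 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split gave 1842 genes and 16 lists for the partner effect at 24 h (highest other 7 and 14), and was in each case the 1 split with as many. At 48 h it gave 5352 genes (highest other 0, 1 split with as many) and 15 lists (highest other 16, 3 splits with as many). For time it gave 11478 genes and 17 lists with the control partner (highest other 0 and 15) and 11207 genes and 12 lists with the shFabp7 partner (highest other 0 and 11), each in 1 split. Mixed groups thus gave nearly as many lists as the real ones under the preset correlation. Each side of a mixed split held more libraries of 1 real group than of the other. Part of the real difference therefore stayed in it. The real difference also entered the spread within each side of a mixed split, which lowers its number of genes. These splits cannot show how many genes or lists would pass without a difference, and neither number alone is given weight.

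The first pattern weighed is that ribosome biogenesis, unfolded protein response, glycolysis and cell cycle lists were higher with the shFabp7 partner at 48 h. Scaling by library totals left the lowest of the 4 medians at 0.22, and subtracting the trend on GC content and transcript length left it at 0.29, which argues against either as the whole cause. A shift along the time course would move the 4 lists alike once multiplied by the sign of their time effect. Ribosome biogenesis stood at -0.58 and glycolysis at 0.32. This prediction holds only if each list keeps its direction between and after the sampled times. The sampled times cannot show that, so such a shift stays open. A biological effect of the partner's shFabp7 stays a hypothesis, found and examined on the same data. Differences between library or culture batches were not tested, since the labels give none.

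The second pattern is that the interferon gamma response list was lower at 48 h while Ifng was higher. The highest list median under RLE, upper-quartile and total-count scaling was -0.14, which argues against scaling. The neutrophil, monocyte and dendritic cell lists lost 0.0367 CPM for each CPM that the interferon list lost (30.6, SE 19.1, against 833.0, SE 181.0). A bound of 1 in 3 had been set beforehand against fewer such cells, but it assumed how many interferon list transcripts they hold, which was not measured. Fewer cells of a type can lower a list by no larger share than markers that only those cells express. Whether T cells also express members of these marker lists was not tested. With TMM scaling the neutrophil list lost 50.5% (SE 10.3), the monocyte list 7.75% (SE 3.51) and the dendritic cell list 4.21% (SE 5.34), against 8.80% (SE 1.85) for the interferon list. By library totals alone each share was larger. The sums went from 131 to 114 CPM for the monocyte, 385 to 348 for the dendritic cell and 10329 to 8885 for the interferon list. Fewer such cells and lower expression therefore cannot be told apart here, since the neutrophil share is larger and the other 2 differ from the interferon share by less than 2 SE. A later position on the time course would lower this list and ribosome biogenesis together, but their medians were -0.16 and 0.58. This too holds only if both lists keep falling between and after the sampled times. The neutrophil markers summed to only 12.7 against 6.31 CPM, beside 9467 against 8634 CPM for the interferon list. The neutrophil share thus rests on a small sum. A weaker response of the T cells to interferon gamma and fewer such cells both stay open, and these values do not rank them. No protein or signalling measure was used here.

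The third pattern is that neutrophil marker transcripts were lower with the shFabp7 partner at 48 h. Of the neutrophil and monocyte lists 7 changed markers fell, S100a8, S100a9, Lcn2, Ngp, Tyrobp, Fcer1g and Lyz2, and none rose. The first 4 of them are the pattern itself, and the monocyte list did not pass (camera, adjusted p = 0.113). Fewer neutrophils and other myeloid cells in the shFabp7 libraries therefore cannot be told apart from lower expression in the cells present. Of the 7, Lcn2 is also in the epithelial list and Tyrobp and Fcer1g in the natural killer list, and the calls of Ngp, Fcer1g and Lyz2 were lost without shFabp7 replicate 1, as well as control replicate 2 for Ngp, control replicate 1 for Fcer1g, and control replicate 1 or shFabp7 replicate 2 for Lyz2 (adjusted p up to 0.0705, 0.180 and 0.111). A larger share of T cells against all other types would lower B cell markers alike. The B cell median was 0.01, which lay 1.12 above the neutrophil median (permutation p = 0.00055 across genes, which are not independent replicates). The neutrophil list was singled out by its fall and the p-value takes no account of that, so no conclusion is drawn from it. The B cell median itself argues against a larger share of T cells as the whole cause. Other medians were -0.40 for basophil, -0.40 for epithelial, -0.26 for erythroid and platelet, -0.19 for monocyte, -0.10 for natural killer, 0.00 for dendritic and 0.09 for plasma cell markers, so a larger share of T cells stays open as part of the cause. S100a9 stood at 2.38 ± 0.991 and Lyz2 at 1.85 ± 0.358 CPM with the control partner, and how the cells were collected was not given in the sources used here.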

How the results depend on the processing

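Scaling by library totals alone was chosen only after the main result was seen, though before its own values were. When the fold had to exceed 1.2, 14 genes passed for the partner effect at 24 h (1842 without that bound), 1005 at 48 h (5352) and 13 for the difference between them (949). The median absolute log2 fold change of the genes called without that bound was 0.25, 0.32 and 0.35. With an estimated correlation 0 lists passed at 24 h, 2 at 48 h, 2 for the difference, 1 for time with the control partner and 1 with the shFabp7 partner, and by fry 36 and 32 lists passed for time. Leaving out 1 library gave 949 to 2525 genes at 24 h (949 without control replicate 1, 1045 without shFabp7 replicate 1) and 319 to 1680 for the difference. For the difference the numbers were 513 and 589 without control replicates 2 and 3 at 24 h, 628, 319 and 342 without shFabp7 replicates 1, 2 and 3 at 24 h, 1680, 588 and 564 without control replicates 1, 2 and 3 at 48 h, and 589, 569 and 569 without shFabp7 replicates 1, 2 and 3 at 48 h. The other counts of genes stayed within 1.5 times. The cause of these moves was not tested.

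The correlation of the partner effects across genes was 0.248 (Pearson) and 0.418 (Spearman), 0.455 and 0.545 among genes with at least 1 CPM in 3 samples, and 0.340 and 0.559 among genes past the threshold at 1 of the times only. Leaving out 1 library gave 0.199 to 0.248 and 0.356 to 0.404. Some values not past the threshold in the main test changed sign, Fabp5 over time with the control partner to 0.0663 by library totals and between -0.22 and 0.0472 without 1 library, Fabp5 over time with the shFabp7 partner between -0.0257 and 0.0949, the Fabp5 difference between -0.0125 and 0.26, and the Fabp3 difference, which rests on few counts, between -4.02 and 0.31. Fabp5 passed over time without control replicate 3 at 24 h (-0.22 with the control partner) and by library totals (0.21 with the shFabp7 partner). Of the calls and non-calls of named genes, 4061 stayed the same and 482 were lost without 1 library, and 5544 stayed and 379 were lost under the other settings. These numbers pool fits and comparisons. Counted by gene, 37 of 105 named calls at 24 h and 21 of 147 at 48 h were lost in at least 1 fit without a library. So were 50 of 83 for the difference, 2 of 165 for time with the control partner and 2 of 164 with the shFabp7 partner. For lists 416 stayed and 28 were lost without 1 library, and 322 and 80 under the other settings. The replicate number as a block gave 1777, 5195, 862, 11388 and 11120 genes, and over all pairs of groups replicates of the same number correlated at -0.129 to 0.0759 and others at -0.119 to 0.194. Same numbers correlated best only between groups that share neither time nor partner (0.0231 to 0.0759, others at most 0.0013) and never over 0.1, so the libraries were not treated as paired. Genes at a few counts, such as the Fabp family besides Fabp5, were measured with little precision. Whether depth or absence of the transcript was the reason was not tested.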

Other observations

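The observation on Ifngr1 was chosen only after the result was seen. Ifngr1, the interferon gamma receptor chain that binds the cytokine, was looked at after the interferon gamma response list had been seen to fall, and it was lower with the shFabp7 partner at 24 h (log2 -0.42 ± 0.06, adjusted p = 3.1e-05) and at 48 h (-0.48 ± 0.06, adjusted p = 8.4e-08). The inhibitory receptor and exhaustion list had 5 of 15 members up and 3 down at 48 h (camera, adjusted p = 0.545), with Tigit at 0.31 ± 0.05, adjusted p = 2.1e-05 and Vsir at -0.24 ± 0.05, adjusted p = 2.2e-04. T cell identity genes went both ways at 48 h, 5 up and 6 down of 22, among them Thy1 (0.32 ± 0.05, adjusted p = 5.7e-06) and Cd8a (-0.23 ± 0.05, adjusted p = 0.00143). Of chemokines and their receptors, 4 rose and 5 fell of 20 at 48 h. Ccl3 and Ccl4, which attract effector cells, rose by 0.91 ± 0.06, adjusted p = 1.7e-11 and 0.68 ± 0.07, adjusted p = 7.5e-08, and the chemokine receptor gene Cxcr4 fell at both times (-0.48 ± 0.06, adjusted p = 1.5e-05 and -0.47 ± 0.06, adjusted p = 3.3e-07).

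Of the core clock list, 7 of 18 members fell and 3 rose at 48 h (8 and 3 adjusted over the list alone) and the list did not pass (camera, adjusted p = 0.139). The clock output gene Dbp fell (-0.52 ± 0.09, adjusted p = 1.5e-05), as did Rora (-0.37 ± 0.06, adjusted p = 1.5e-05), while the clock repressors Nfil3 and Bhlhe40 rose (0.49 ± 0.06, adjusted p = 1.6e-07 and 0.42 ± 0.06, adjusted p = 1.1e-06). In the TGF-beta response list 5 of 14 fell and 2 rose, with Skil at -0.31 ± 0.05, adjusted p = 1.2e-05. In the integrated stress response list 5 of 23 rose and 1 fell, with the serine pathway gene Shmt2 at 0.43 ± 0.08, adjusted p = 5.6e-04 and the stress factor Ddit3 at -0.46 ± 0.07, adjusted p = 9.2e-06. Neither list passed (adjusted p = 0.175 and 0.649). Natural killer, epithelial and basophil lists did not pass at 48 h either (adjusted p = 0.175, 0.117 and 0.185).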
